A study of Arabidopsis thaliana with 6 samples.

How the data were processed

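RNA was measured by sequencing in the aerial parts of 9-day-old Arabidopsis thaliana seedlings of 2 genotypes, wild-type Col and cpl2-2, with 3 libraries of each. Per the labels, the plants grew at 23 ± 2 °C under 16 h light and 8 h dark, total RNA was extracted with an RNeasy Plus kit, and libraries were made with NEBNext Ultra II Directional, a kit that keeps the strand. The design text calls the 3 replicates of each genotype biological. Genotype and replicate number were taken from the labels of each sample.

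The authors deposited 1 table of whole-number read counts per gene, with 1 column per library and no normalization; the unit was read from the deposited values, which are whole numbers with a different total in each column. The aligner HISAT2 2.0.5 and the genome build TAIR10 are named in the submitters' processing notes. The program that counted reads, whether it used strand, and the annotation release are not given in the sources used here. Without a stated strand setting, reads of a gene and of a gene overlapping it on the opposite strand cannot be told apart, so values of such genes are uncertain, and so are those of near-identical copies, between which reads could be split. Among the genes named, CPL1, FLC, AT5G59230, AT3G30120, ASY1, MRD1, EARLI1, AT5G51190, COR15B, P5CS1, MAD2, XTH15, CHS, GSTF12, ARP6, HSP101, FRO3, ECT3, PAP17, LHCB1.3, CDKC2 and CASP1 overlap an annotated gene on the opposite strand and TSO2 one on its own strand.

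Coordinates are those of the deposited table (TAIR10). Its column of gene names repeats the locus identifiers, so symbols were taken from the RefSeq gene table of assembly TAIR10.1, matched by locus tag; 37570 of 38192 identifiers (98.4%) matched. Gene families were therefore built from these symbols rather than from symbols in the deposited table, and from the table's own column of transcription factor families. Genes in the fixed lists were matched by locus identifier.

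Library totals ran from 18299294 to 21098728 counts. Of 38192 genes, 25558 had a count in any library and 19302 passed edgeR's filterByExpr with the genotypes as groups. At this depth a gene at 1 CPM holds about 20 counts in a library, so folds of genes under 1 CPM rest on few counts. Counts were normalized with TMM factors and tested with edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3; genotype the only term), with Benjamini-Hochberg adjustment over all genes tested. A gene was called at an adjusted p under 0.05. All adjusted p-values of single genes come from this test unless another is named. Fold changes are log2 of cpl2-2 over wild type with the standard error (SE) from the quasi-likelihood fit. Levels are counts scaled to a common library total with the TMM factors (CPM), as mean ± SD over the 3 libraries. The common biological coefficient of variation was 0.0566. Pearson correlations and principal components used log2 CPM with a prior count of 2. Shares of library counts were compared between genotypes by a two-sided exact permutation test, which cannot give a p below 0.1 with 3 libraries against 3.

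Before the data were examined, 23 gene lists holding 399 distinct genes, their tests, the alternatives and the rule for naming genes were fixed. The shares of counts from the photosynthesis genes and from the 10 most abundant genes were not named in that plan, and neither were the lists matched on abundance. Each of those 10000 lists drew, for every photosynthesis gene, 1 of the 50 genes nearest in mean CPM whose description names no chloroplast or photosynthetic product. Lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes, adjusted over the 22 lists tested. Camera with an estimated correlation and fry were run as alternatives. Calls of list members are counted over all genes tested and, separately, adjusted over the list alone. Families with at least 10 tested genes (167 families) were tested for over-representation among genes called higher or lower by two-sided Fisher's exact test against the tested genes with a symbol (8232) or with a transcription factor family (1531), adjusted over families and directions. Genes, not samples, are the units of that test. After the results were seen, the family test was repeated with library totals, and the calls in each family were set beside those in 10000 sets of other genes with a symbol, each drawing 1 of the 50 genes nearest in mean CPM for every member.

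The genes named are CPL2, CPL1, CPL3, FLC, FT, SOC1 and SVP; the 10 with the largest rise and the 10 with the largest fall among called genes with a mean of at least 1 CPM and no overlap between the genotypes; and up to 4 called members with the smallest p from each fixed list. Other genes are named to describe a list or a small count, and were chosen after their values were seen. Where wild type held few counts in total, the ratio of the summed counts is given with an exact 95% interval (from the binomial distribution of the 2 sums), which covers counting error only.

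Alternatives were DESeq2's size factors in edgeR (RLE), library totals with no composition factor, no filter on low counts, nuclear genes only, the replicate number as a block, each library left out in turn, the DESeq2 Wald test (DESeq2 1.42.0), limma-voom, an adjusted p under 0.01 and a change of at least 2-fold. The scripts were tested on simulated counts drawn from the means and library sizes of these libraries, with 200 of 19090 tested genes changed. For simulated cpl2-2 against wild type, 60 of 100 genes changed 1.5-fold and 84 of 100 changed 2-fold were recovered, and 7 of 151 calls (4.64%) were false. The raised list was called and 0 of 20 unchanged lists were. Figures were drawn with matplotlib 3.10.9.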

Results

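Transcript levels were measured in the aerial parts of 9-day-old Arabidopsis seedlings of the wild type (accession Col) and of cpl2-2, which the labels describe as a knockout of CPL2. CPL2 encodes a phosphatase-like protein of the family that acts on the C-terminal domain of RNA polymerase II. The comparison asks which transcripts differ between the genotypes. There were 3 libraries per genotype. The wild-type libraries held 20756428, 20905810 and 21098728 counts and the cpl2-2 libraries 18299294, 20653008 and 20129793 counts.

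CPL2 (AT5G01270, chromosome 5, 107547 to 112324, minus strand) was lower in every cpl2-2 library than in every wild-type library. It had 391, 378 and 393 counts in the wild-type libraries and 198, 229 and 222 in the cpl2-2 libraries. The level fell from 19.0 ± 0.47 to 10.7 ± 0.15 CPM (SD, n = 3; log2 fold change -0.82, SE 0.10, adjusted p = 6.0e-09), which left 56.6% of the wild-type level. The counts cover the whole gene, and the position of the lesion is not given in the sources used here, so the remaining reads do not show whether an intact transcript was made. Of the 5 annotated genes on each side of CPL2, 5 had enough counts for the test, and 0 of them were called by edgeR, DESeq2 or limma-voom, with 0 at an unadjusted p under 0.05. The related phosphatase genes CPL1 (AT4G21670; log2 fold change -0.23, SE 0.10, adjusted p = 0.072) and CPL3 (AT2G33540; -0.11, SE 0.11, adjusted p = 0.51) were not called. Without wild type replicate 3, CPL1 passed the threshold (adjusted p = 0.049).

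Of 19302 genes tested, 5277 (27.3%) differed between the genotypes, 2717 of them higher and 2560 lower in cpl2-2. Most changes were small, with a median absolute log2 fold change of 0.35 among called genes. Changes of at least 2-fold were mostly rises, with 592 genes higher and 98 lower. Of the 592, 320 had a mean under 1 CPM in the wild type. The CPM values of the genotypes did not overlap for 7529 genes (39.0%), where chance gives 10%. The libraries grouped by genotype. Pearson's r across genes (which are not independent replicates) was 0.989 within each genotype and 0.973 to 0.974 between genotypes, and the first principal component, with 58% of the variance, separated them. With library totals in place of TMM factors, 3952 genes were higher and 1666 lower, so the near-even split of all calls depends on the scaling, whereas 672 rises and 83 falls reached 2-fold.

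**Figure D1:**
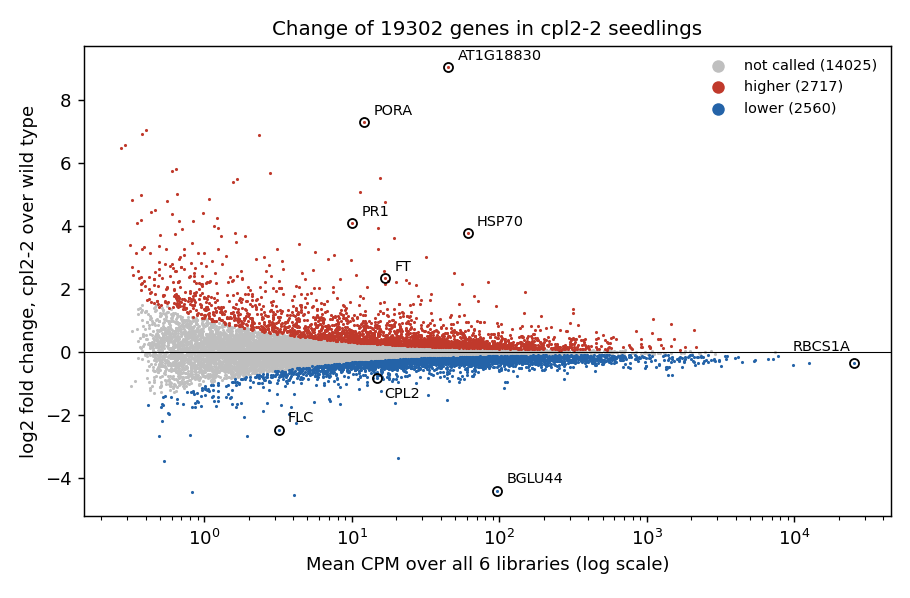
Each point is 1 of the 19302 tested genes, with its mean CPM over the 6 libraries on a log axis and its log2 fold change, cpl2-2 over wild type, on the vertical axis. Red and blue points are the 2717 genes called higher and the 2560 called lower, and circles mark 9 named genes, from AT1G18830 (9.05) to BGLU44 (-4.39).

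The 10 largest rises were in genes with a mean under 1.2 CPM in the wild type. AT1G18830 (chromosome 1, 6489233 to 6494634), a homologue of the vesicle coat protein SEC31, had 1, 0 and 9 counts in the wild-type libraries and 1723, 1914 and 1804 in cpl2-2 (log2 fold change 9.05, SE 0.17, adjusted p = 3.8e-39), a ratio of summed counts of 552 with a 95% counting interval of 300 to 1151. As 9 of the 10 wild-type counts were in replicate 3, the log2 fold change of AT1G18830 was 11.52 without it, and 9.90 with limma-voom. PORA (AT5G54190), a protochlorophyllide oxidoreductase of chlorophyll synthesis, rose from 0.147 ± 0.050 to 24.2 ± 2.34 CPM (log2 fold change 7.30, SE 0.22, adjusted p = 2.3e-30; ratio of counts 165, interval 86.7 to 362). SUC5 (AT1G71890), a sucrose transporter, rose from 0.653 ± 0.105 to 30.5 ± 0.091 CPM. AT5G47600, encoding a small heat shock protein, rose from 0.637 ± 0.0051 to 22.1 ± 2.35 CPM. ASY1 (AT1G67370), a meiotic chromosome axis gene, rose from 1.16 ± 0.51 to 32.1 ± 1.85 CPM, and AGO5 (AT2G27880), an Argonaute gene, from 0.098 ± 0.098 to 5.44 ± 0.515 CPM (ratio of counts 55.7, interval 25.3 to 153). ASY1 overlaps an annotated gene on the opposite strand. The cupredoxin gene AT4G33930 had 2 counts over the wild-type libraries and 284 over cpl2-2, a ratio of 144 with a 95% counting interval of 39.5 to 1194. AT5G59230 (ratio 50.2, interval 19.3 to 186), AT3G30120 (46.4, interval 18 to 172) and AT2G44240 (31.9, interval 12.2 to 119), each with 4 wild-type counts in total, completed the 10 largest rises. Single wild-type libraries moved the log2 fold changes of AGO5 (5.71, and 6.62 without replicate 2), AT3G30120 (5.42, and 8.95 without replicate 3) and AT2G44240 (4.87, and 8.41 without replicate 1).

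The largest falls were in AT2G05040, BGLU44 and MRD1. AT2G05040 (chromosome 2, 1783119 to 1786463), annotated as a transposable element gene, fell from 7.76 ± 0.30 to 0.319 ± 0.309 CPM (log2 fold change -4.53, SE 0.32, adjusted p = 2.7e-16). The log2 fold change of AT2G05040 was -5.40 without cpl2-2 replicate 2 and -5.34 with limma-voom. The beta-glucosidase gene BGLU44 (AT3G18080; chromosome 3, 6191461 to 6194452) fell from 185 ± 4.0 to 8.80 ± 1.62 CPM (-4.39, SE 0.07, adjusted p = 3.4e-42). MRD1 (AT1G53480), which overlaps genes on the opposite strand, fell from 37.4 ± 3.90 to 3.66 ± 0.41 CPM (-3.36, SE 0.11, adjusted p = 9.4e-29). The other falls among the 10 largest were EARLI1, a lipid transfer protein gene (-2.67), FLC (-2.46), the zinc finger gene STZ (-2.25), AT3G26460, related to major latex proteins (-2.07), the ethylene response factor gene AT5G51190 (-1.96), the glutaredoxin gene AT4G15690 (-1.87) and AT4G29780 (-1.74).

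Of the genes that control flowering time, 7 of 15 tested repressors fell and 6 of 13 tested promoters rose in cpl2-2. FLC (AT5G10140; chromosome 5, 3173382 to 3179448), the MADS-box repressor of the floral transition, fell from 5.40 ± 0.43 to 0.986 ± 0.278 CPM (log2 fold change -2.46, SE 0.25, adjusted p = 5.3e-11), or 5.49-fold. Its relative MAF5 fell from 11.6 ± 0.043 to 4.43 ± 0.069 CPM (-1.38, SE 0.14, adjusted p = 3.8e-11). FT (AT1G65480; chromosome 1, 24331373 to 24333999), which encodes the mobile flowering signal, rose from 5.50 ± 0.64 to 28.2 ± 0.74 CPM (2.36, SE 0.11, adjusted p = 3.3e-23), or 5.13-fold. SOC1 (AT2G45660), a floral integrator, rose from 10.4 ± 0.36 to 20.5 ± 1.44 CPM (0.98, SE 0.10, adjusted p = 6.1e-11).

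Among the 15 tested floral repressors, 7 fell and 1 rose (9 and 1 adjusted over the list alone). Camera called this list lower (adjusted p = 0.0065), but not with an estimated correlation (adjusted p = 0.11). Besides FLC and MAF5, the falls were FLM (-0.47), MAF2 (-0.42), TEM1 (-0.30), TEM2 (-0.62) and TOE2 (-0.32); the rise was BFT (1.61), at 0.506 ± 0.026 CPM in the wild type. SVP (AT2G22540), which acts with FLC, was at 77.1 ± 1.03 CPM in the wild type and 80.1 ± 0.44 in cpl2-2 and was not called (0.05, SE 0.05, adjusted p = 0.45). Among the 13 tested floral promoters, 6 rose and 1 fell, with the same counts adjusted over the list alone. Camera called the promoters higher (adjusted p = 0.00048), but not with an estimated correlation (adjusted p = 0.078). FUL rose from 3.09 ± 0.15 to 11.7 ± 0.72 CPM (1.92), TSF, the closest relative of FT, by 0.83, AGL24 by 0.59 and SPL3 by 0.53 on the log2 scale. GI, a clock gene that promotes FT expression, was the member that fell (-0.90, SE 0.10, adjusted p = 2.1e-10), while CO was at 3.56 ± 0.32 CPM in the wild type and 4.02 ± 0.31 in cpl2-2 (adjusted p = 0.58). LFY and AP1, which specify floral meristems, had too few counts for the test: LFY had 2 counts over the wild-type and 26 over the cpl2-2 libraries (ratio 13.2, 95% counting interval 3.3 to 114), and AP1 had 3 and 37 (12.5, interval 3.96 to 63.4). Of the other members with too few counts, the promoter AGL19 had 8, 4 and 29 counts in the wild type and 3, 1 and 5 in cpl2-2, and the repressor TFL1 had 2, 2 and 1 and 21, 3 and 3 (ratio 5.47, interval 2.08 to 18). FLC overlaps an annotated gene on the opposite strand.

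**Figure D2:**
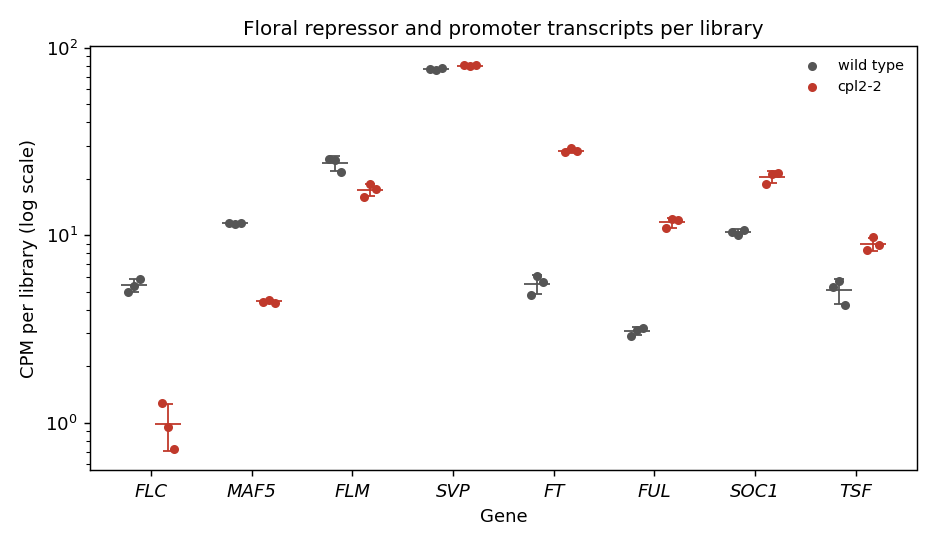
CPM of 8 flowering genes in each library on a log axis, in the wild type (grey) and cpl2-2 (red), with points for the 3 libraries of a genotype and marks with bars for their mean ± SD. FLC, MAF5 and FLM were lower in cpl2-2, FT, FUL, SOC1 and TSF were higher, and SVP was at 77.1 CPM in the wild type and 80.1 in cpl2-2.

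Genes known to set FLC activity were called in few cases. Among 16 tested FLC activators, 3 fell (3 adjusted over the list alone): VIP4 (-0.28), ARP6 (-0.32) and HUB1 (-0.33). The list was not called (camera adjusted p = 0.62), and its median log2 fold change (0.01) and mean (-0.02) differed in sign. The calls of ARP6 and HUB1 were lost without wild type replicate 3 (adjusted p = 0.059 and 0.098), that of ARP6 also without cpl2-2 replicate 1 (0.052) and that of HUB1 also with library totals (0.061). Of the 8 genes of the autonomous pathway, which represses FLC, 1 was called over all genes (FVE, -0.17, adjusted p = 0.027) and 0 adjusted over the list alone, with 1 of 8 at an unadjusted p under 0.05 in edgeR and 1 called by DESeq2 and by limma-voom. The FVE call was lost without wild type replicate 3 (adjusted p = 0.27) and without cpl2-2 replicates 2 or 3 (0.059 and 0.072), and with library totals (0.20). The autonomous pathway list was not called (camera adjusted p = 0.62), and with library totals 1 of its genes was higher and 0 lower.

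Of 19 tested defence genes linked to salicylic acid, 10 rose and 9 did not pass the test. PR1 (AT2G14610), a pathogenesis-related gene and a marker of salicylic acid signalling, rose from 1.09 ± 0.061 to 19.1 ± 2.48 CPM (4.11, SE 0.17, adjusted p = 3.1e-25), or 17.3-fold. PR5 rose from 13.9 ± 1.03 to 24.6 ± 2.66 CPM (0.82, SE 0.10), PBS3, an enzyme of salicylic acid synthesis, from 2.30 ± 0.33 to 6.61 ± 1.02 CPM (1.52, SE 0.20), and PAD4, an immune regulator, from 5.65 ± 0.29 to 11.3 ± 1.03 CPM (0.99, SE 0.14). Adjusted over the list alone, 12 rose and 1, WRKY70, fell (-0.14). EDS1, the partner of PAD4, was at 29.0 ± 2.01 and 27.7 ± 2.17 CPM (adjusted p = 0.58). The list was called higher (camera adjusted p = 7.2e-07, and adjusted p = 0.043 with an estimated correlation).

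Transcripts of the jasmonate and wounding list moved in both directions. Of 21 tested members, 9 rose and 6 fell (9 and 6 adjusted over the list alone), and the list was not called (camera adjusted p = 0.072). The plant defensin gene PDF1.3 rose from 1.59 ± 0.51 to 12.3 ± 1.21 CPM (2.95, SE 0.18), and PR4, a chitin-binding protein gene, from 38.2 ± 2.35 to 59.6 ± 3.0 CPM (0.64, SE 0.06). The jasmonate synthesis genes AOC1 (-0.98, SE 0.08) and AOS (-0.34, SE 0.03) fell, as did the vegetative storage protein genes VSP1 (-0.41) and VSP2 (-0.51). The PDF1 genes are near-identical copies, so the value of each is uncertain.

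In the heat shock list, 2 of 7 tested members rose and 1 fell (2 and 1 adjusted over the list alone). HSP70 (AT3G12580), a cytosolic chaperone gene, rose 13.9-fold, from 8.16 ± 0.85 to 113 ± 6.19 CPM (3.80, SE 0.07, adjusted p = 2.4e-38), and HSP90-1 rose from 10.8 ± 1.33 to 27.9 ± 1.48 CPM (1.37, SE 0.10, adjusted p = 2.6e-16). HSP101, a disaggregase needed for heat tolerance, fell (-0.36, SE 0.13, adjusted p = 0.035). The list was called higher (camera adjusted p = 1.3e-10, and adjusted p = 0.035 with an estimated correlation). HSP101 lost its call without any 1 wild-type library (adjusted p = 0.053, 0.089 and 0.073 without replicates 1, 2 and 3), without cpl2-2 replicate 1 (0.12) or 3 (0.077), with DESeq2 (0.061) and with library totals (0.091). The small heat shock genes HSP17.8 and HSP18.2 were under 2 CPM in both genotypes and were not called, and HSP17.6II, with too few counts for the test, had 0 counts in the wild type and 16 in cpl2-2 (at least 3.91-fold by the lower 95% counting limit, and 5.4-fold against a floor of 3 counts over the group).

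Genes that respond to abscisic acid, drought and cold were divided, and the list was called higher (camera adjusted p = 0.0018; not called with an estimated correlation, adjusted p = 0.079). Of 21 tested members, 11 rose and 7 fell, with the same counts adjusted over the list alone. COR15B, a cold-regulated chloroplast protein gene, rose from 62.9 ± 3.46 to 236 ± 5.06 CPM (1.91, SE 0.04, adjusted p = 9.6e-36), and P5CS1, an enzyme of proline synthesis, from 25.0 ± 1.82 to 42.2 ± 2.30 CPM (0.75, SE 0.07). KIN1 rose from 0.735 ± 0.173 to 7.98 ± 1.40 CPM (3.43, SE 0.24) and its neighbouring near-identical copy KIN2 from 263 ± 11.4 to 351 ± 39.7 CPM (0.42, SE 0.04), so the division of reads between these copies is uncertain. RD29B, a relative of RD29A, rose from 4 counts over the wild-type libraries to 57 over cpl2-2 (3.73, SE 0.70; ratio 14.4, 95% counting interval 5.34 to 54.8). RD29A fell from 50.3 ± 2.70 to 32.8 ± 1.89 CPM (-0.62, SE 0.07), and CBF1 (-2.66, SE 0.65) and CBF3 (-1.53, SE 0.48), regulators of the cold response, fell from 0.864 ± 0.290 and 1.34 ± 0.586 CPM.

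Nuclear genes of photosynthesis fell by small amounts. Of 25 members, 21 fell and 3 rose (21 and 3 adjusted over the list alone), with a median log2 fold change of -0.28, and the list was called lower (camera adjusted p = 6.8e-19, and adjusted p = 0.035 with an estimated correlation). LHCA1, a light-harvesting protein gene of photosystem I, fell from 1593 ± 15.2 to 1123 ± 20.7 CPM (-0.50, SE 0.02, adjusted p = 1.4e-22). RBCS1A, a Rubisco small subunit gene and the most abundant of the list, fell from 28327 ± 588 to 22197 ± 673 CPM (-0.35, SE 0.02, adjusted p = 3.8e-23). LHCB1.2 fell by 0.73 and LHCB1.3 by 0.39 on the log2 scale; the members that rose were LHCB2.1 (0.15), LHCB2.2 (0.46) and LHCB4.2 (0.25). The LHCB1, LHCB2 and RBCS genes are close copies of one another, so their single values are uncertain. The 25 genes took 11.3% ± 0.105 of all counts in the wild type and 9.71% ± 0.114 in cpl2-2 (SD, n = 3; exact permutation p = 0.1, the smallest possible here). Abundant genes in general tended to be lower: among 10000 lists of other genes matched on mean CPM, medians ran from -0.32 to 0.22 around -0.07, and 9 were as low as that of the photosynthesis list.

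The shares of counts from organelles and transposons were small. Chloroplast genes took 0.0297% ± 0.0068 of counts in the wild type and 0.0252% ± 0.00067 in cpl2-2 (SD, n = 3; exact permutation p = 0.2), and mitochondrial genes 0.000316% ± 0.000094 and 0.000547% ± 0.000058 (exact permutation p = 0.1, the smallest possible). Transposable element genes took 0.0585% ± 0.00073 and 0.0683% ± 0.0014 (exact permutation p = 0.1, the smallest possible). The 10 most abundant genes took 9.76% ± 0.083 and 8.49% ± 0.124 (n = 3, exact permutation p = 0.1).

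Of 21 tested clock genes, 11 fell and 3 rose (12 and 4 adjusted over the list alone). GI fell from 24.5 ± 2.35 to 13.1 ± 1.51 CPM (-0.90, SE 0.10), PRR7 from 10.2 ± 1.13 to 5.63 ± 0.74 CPM (-0.86, SE 0.14) and GRP7, a clock-controlled RNA-binding protein gene, from 1666 ± 68.8 to 1374 ± 114 CPM (-0.28, SE 0.03). ELF4, a component of the evening complex, rose from 87.6 ± 2.27 to 120 ± 3.68 CPM (0.46, SE 0.04, adjusted p = 1.1e-11). The morning gene LHY was under 1.5 CPM in both genotypes and CCA1 had between 4 and 12 counts in each library. The list was called lower (camera adjusted p = 0.030), but not with an estimated correlation (adjusted p = 0.17) or without wild type replicate 3 (adjusted p = 0.068), and with library totals 11 fell and 5 rose. The time of day of harvest is not given in the sources used here.

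In the cell cycle list, 7 of 24 members fell, 17 did not pass the test, and the list was called lower (camera adjusted p = 0.0065; adjusted p = 0.14 with an estimated correlation). Adjusted over the list alone, 7 fell as well. TSO2, a subunit of ribonucleotide reductase, fell by 0.28, the spindle checkpoint gene MAD2 by 0.50, the cyclin gene CYCB2-2 by 0.69 and the cytokinesis kinesin gene HIK by 0.43 on the log2 scale. TSO2 overlaps another gene on its own strand.

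Genes of flavonoid and glucosinolate synthesis included both rises and falls. CHS, an early flavonoid enzyme gene, rose from 526 ± 8.33 to 706 ± 4.72 CPM (0.43, SE 0.03, adjusted p = 1.5e-17), while DFR, needed for anthocyanin, fell from 147 ± 3.29 to 77.1 ± 1.39 CPM (-0.93, SE 0.04, adjusted p = 6.9e-23), as did GSTF12, a carrier of anthocyanin to the vacuole, by 0.76 and LDOX by 0.55 on the log2 scale. Of 20 flavonoid and anthocyanin genes, 7 rose and 8 fell, with the same counts adjusted over the list alone. The list was called lower (camera adjusted p = 0.035), with a mean of -0.15 but a median of 0.05. That call was lost with an estimated correlation (adjusted p = 0.14), with library totals (adjusted p = 0.089) and without cpl2-2 replicate 2 (adjusted p = 0.062). Of 19 tested glucosinolate genes, 9 fell and 3 rose (10 and 4 adjusted over the list alone). The chain-elongation gene MAM1 fell by 0.46, the side-chain gene AOP2 by 0.63, CYP79F1 by 0.24 and the regulator MYB34 by 0.34 on the log2 scale. The list was called lower (camera adjusted p = 0.014), but not with an estimated correlation (adjusted p = 0.12) or with library totals (adjusted p = 0.060; 7 lower and 5 higher).

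**Figure D3:**
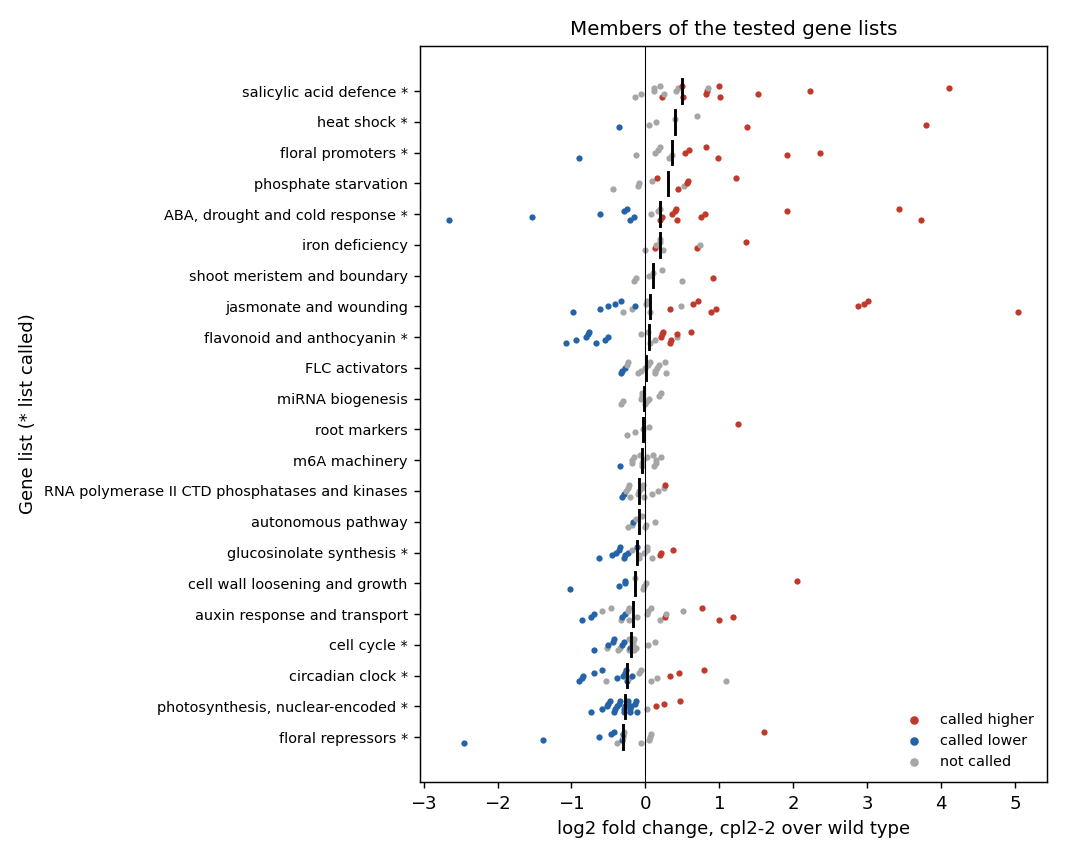
Log2 fold change, cpl2-2 over wild type, of each tested member of the 22 tested gene lists, sorted by list median (black bar), with members called higher in red, called lower in blue and not called in grey, and asterisks on the 10 lists called by camera. The salicylic acid defence list has the highest median (0.50) and the floral repressor list the lowest (-0.31).

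Leaving out CPL2, which was in none of the 3 lists described here, genes that act on RNA polymerase II or on RNA itself changed in few cases. Of 15 genes for polymerase subunits and for kinases and phosphatases of its C-terminal domain, NRPB1, the largest subunit, rose (0.27, SE 0.05), and the kinase gene CDKC2 (-0.29, SE 0.06) and its cyclin gene CYCT1-4 (-0.32, SE 0.09) fell, with the same counts adjusted over the list alone; CYCT1-4 lost its call without wild type replicate 2 (adjusted p = 0.095). Of 14 genes for the m6A mark on RNA, the reader gene ECT3 fell (-0.35, SE 0.05), the 1 call also when adjusted over the list alone. Of 10 genes of microRNA biogenesis, 0 were called by edgeR over all genes or adjusted over the list alone, with 3 at an unadjusted p under 0.05, and 0 by DESeq2 or limma-voom. Camera called none of these 3 lists (adjusted p = 0.57, 0.62 and 0.86). With library totals the calls were 2 higher and 2 lower in the polymerase list, 3 higher and 1 lower in the m6A list and 1 higher and 0 lower in the microRNA list, and the median log2 fold changes of the m6A list (-0.04 to 0.02) and the microRNA list (-0.02 to 0.04) turned in sign.

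Among 22 tested auxin genes, 4 rose and 5 fell (4 and 5 adjusted over the list alone; camera adjusted p = 0.86). The auxin-conjugating enzyme genes GH3.5 (1.19, SE 0.13) and GH3.6 (0.99, SE 0.08) rose, while the repressor gene IAA2 (-0.85, SE 0.09) and the efflux carrier gene PIN4 (-0.28, SE 0.05) fell. Of 9 cell wall and growth genes, 4 fell and 1 rose (4 and 1 adjusted over the list alone; camera adjusted p = 0.092). The wall enzyme gene XTH22 fell from 12.2 ± 0.65 to 6.06 ± 0.95 CPM (-1.01, SE 0.13), XTH4 by 0.27 and the expansin genes EXPA5 and EXPA1 by 0.36 and 0.27, and XTH15 rose from 1.13 ± 0.54 to 4.68 ± 1.26 CPM (2.05, SE 0.28). Of 10 phosphate starvation genes, 5 rose (5 adjusted over the list alone; camera adjusted p = 0.072), with the sulfolipid synthesis gene SQD1 at 0.44, the galactolipid synthesis gene MGD2 at 0.57, the phosphatase genes PAP17 and PS2 at 0.58 and 1.23, and SQD2 at 0.16. SQD2 lost its call without wild type replicate 1 (adjusted p = 0.0517) or 3 (0.0524) or cpl2-2 replicate 3 (0.0573). Of 9 iron deficiency genes, 3 rose (4 adjusted over the list alone, 5 with library totals; camera adjusted p = 0.12). They were FRO3 (0.69, SE 0.13), FRO2 (1.36, SE 0.49) and OPT3 (0.13, SE 0.05). The log2 fold change of FRO2 was 2.49 without wild type replicate 1 and 1.99 with limma-voom. Without single libraries FRO2 and OPT3 lost their calls: without wild type replicate 3 (adjusted p = 0.11 and 0.28), without cpl2-2 replicate 3 (0.16 and 0.12), FRO2 also without wild type replicate 2 (0.24) and cpl2-2 replicate 2 (0.064), and OPT3 also without wild type replicate 1 (0.058) and cpl2-2 replicate 1 (0.22). DESeq2 called neither (adjusted p = 0.34 and 0.084).

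Of the markers of other tissue, 1 of 7 tested meristem and boundary genes and 1 of 5 tested root genes were called. Of 7 tested shoot meristem and boundary genes, STM, which maintains the meristem, rose from 3.92 ± 0.56 to 7.38 ± 0.82 CPM (0.91, SE 0.17, adjusted p = 4.1e-05), the 1 call also when adjusted over the list alone (camera adjusted p = 0.70). Of 5 tested root markers, the endodermis gene CASP1 rose (1.25, SE 0.42, adjusted p = 0.022), the 1 call also when adjusted over the list alone (camera adjusted p = 0.995, with a median of -0.03, or 0.04 with library totals, and a mean of 0.18). The CASP1 call was lost without wild type replicates 1 or 2 (adjusted p = 0.087 and 0.091) and without cpl2-2 replicate 3 (adjusted p = 0.14). CASP1 was at 0.538 ± 0.167 CPM in the wild type. The root beta-glucosidase gene PYK10 was at 313 ± 7.41 and 308 ± 13.5 CPM (adjusted p = 0.61). Of 13 seed storage and late embryo genes, 1 had enough counts for the test, OLEO4, and it was not called (adjusted p = 0.66; 0 at an unadjusted p under 0.05 in edgeR and 0 called by DESeq2 or limma-voom).

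Families were read from the leading letters of the symbols of all tested genes, list members included. A family can therefore hold unrelated genes that share a prefix. Among genes called lower, 5 symbol families were over-represented. PTAC genes, for proteins of the plastid transcription complex, were lower in 12 of 14 cases (85.7%, against 14.7% of all tested genes with a symbol; odds ratio 35.1, Fisher's exact test, adjusted p = 2.2e-06). Ribosomal protein genes were lower under the symbols RPL (15 of 22, adjusted p = 3.0e-06) and RPS (14 of 24, adjusted p = 0.00010); 6 of these RPL and 2 of these RPS genes are described as chloroplast proteins. The other families were EMB, genes named for embryo-lethal mutants (45 of 157, adjusted p = 0.00045), and PDE, named for pigment-defective embryos (10 of 15, adjusted p = 0.00045). With library totals PTAC (9 of 14, adjusted p = 0.00012), RPL (13 of 22, adjusted p = 3.1e-06) and PDE (7 of 15, adjusted p = 0.018) were still over-represented, but RPS was not (8 lower and 4 higher, adjusted p = 0.061), and neither was EMB (27 lower and 19 higher, adjusted p = 0.077). Sets of other genes with a symbol, matched on mean CPM, held a median of 4 lower genes for PTAC, 9 for RPL, 7 for RPS, 28 for EMB and 3 for PDE. Of 10000 such sets, 0 held as many as PTAC or PDE, 34 as many as RPL, 12 as many as RPS and 2 as many as EMB. These falls were small, with median log2 fold changes of -0.26 for PTAC, -0.17 for RPL, -0.14 for RPS, -0.10 for EMB and -0.20 for PDE. Among genes called higher, those with symbols starting with CYP, the prefix of cytochrome P450 genes, were over-represented (38 of 114, 33.3%, against 17.0%). The odds ratio was 2.48 (Fisher's exact test, adjusted p = 0.0013), but with library totals CYP was not over-represented (adjusted p = 0.077). Matched sets held a median of 18 and at most 32 higher genes for CYP, so 0 of 10000 held as many.

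Among genes changed at least 2-fold, 5 families were over-represented, of which NAC and ERF were found by symbol and by transcription factor family. NAC transcription factor genes rose in 10 of 65 cases (15.4%, against 3.72% of transcription factor genes; odds ratio 5.48, adjusted p = 0.011), among them NAC061 (2.30, SE 0.35) and NAC103 (1.55, SE 0.28); under the symbol NAC it was 9 of 49 (adjusted p = 0.0062). Receptor-like protein genes under the symbol RLP rose in 6 of 36 cases (adjusted p = 0.039), CYP genes in 12 of 114 (adjusted p = 0.016) and PDF genes in 4 of 10 (adjusted p = 0.015), which are the defensin genes PDF1.2, PDF1.2b, PDF1.2c and PDF1.3, of which all but PDF1.2c are in the jasmonate list. These 4 are near-identical copies with uncertain single values, which the test takes as separate genes, and over all calls 4 PDF genes rose and 2 fell, with no over-representation (adjusted p = 0.64). Falls of at least 2-fold were 2 of 65 for NAC, 0 of 36 for RLP, 1 of 114 for CYP and 1 of 10 for PDF. Over all calls, Fisher's exact test did not find rises over-represented for NAC (18 of 65, adjusted p = 0.075, and 16 of 49 by symbol, 0.15) or RLP (12 of 36, 0.26). Rises of 2-fold were more frequent among scarce genes (186 of 1316 under 1 CPM, 54 of 6013 at 16 to 64 CPM). The 2-fold calls of these families were not set beside genes of like abundance. Of the 83 ethylene response factor genes in the AP2/ERF family, 6 fell at least 2-fold (adjusted p = 0.018), among them ERF104 (-1.54, SE 0.15) and ERF5 (-1.03, SE 0.17); under the symbol ERF it was 3 of 21 (adjusted p = 0.011). Over all calls these genes were even, with 10 higher and 11 lower in the AP2/ERF family and 4 and 4 under the symbol ERF. The genes named in the families were chosen after their values were seen.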

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

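The count of changed genes, the fall of CPL2 and the excess of 2-fold rises kept their direction and their side of the threshold under every scaling, filter and test that was run. Across RLE factors, library totals, no filter, nuclear genes only, DESeq2 and limma-voom, 4536 to 5618 genes were called, 558 to 696 rose and 77 to 129 fell at least 2-fold, and the log2 fold change of CPL2 ran from -0.83 to -0.75. Leaving out 1 library at a time gave 4524 to 4832 calls, 667 to 697 of at least 2-fold, a CPL2 change of -0.84 to -0.81 (adjusted p from 2.1e-08 to 3.4e-07) and 9 to 10 called lists. With library totals the genes called lower dropped from 2560 to 1666, since without a composition factor the median of all genes moved from -0.0017 to 0.066. Asking for a 2-fold change left 690 of the 5277 calls, 592 higher and 98 lower. Camera with an estimated correlation called 3 lists in place of 10. Among the lists that lost their call, the estimate was below the preset 0.01 for floral promoters (-0.046) and floral repressors (-0.040). The same held for the abscisic acid (-0.019), flavonoid (-0.033) and glucosinolate (-0.022) lists. It was above 0.01 for the clock (0.018) and cell cycle (0.031) lists. Loss of these calls therefore does not by itself show correlation between members. The families over-represented went from 6 to 10 when families of at least 5 genes were tested, which adds families; with calls of at least 2-fold they were 7, counting NAC and ERF by symbol and by family, and with library totals, an alternative added after the results were seen, they were 3. With the replicate block, 5228 genes were called, 5156 of them also called without it, and 10 lists. Deviations of libraries with the same number correlated at -0.012, 0.010 and 0.013, and not every library correlated best with its own number. No pairing by number was thus visible, but values this close to none cannot exclude a shared batch. Of 1157 values of 89 named genes under the alternatives, 1124 stayed on their side of the threshold, 32 of 9 genes lost the call and 1 gained it; of 286 values of the 22 lists, 270 stayed, 11 lost and 5 gained the call, and the cause was not tested. The gains were 1 call without wild type replicate 3 (CPL1) and 5 lists with fry, which does not compare a list with other genes. Depth limits genes under 1 CPM, of which 186 of 1316 rose and 32 fell at least 2-fold; in the simulated data 60 of 100 changes of 1.5-fold were recovered.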

Other observations

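The SWR1, rapid stress, floral organ and afternoon lists were chosen after the results were seen, and so were all tests here except those of the afternoon genes, whose reading beside the evening genes was added later, and of the splits. Genes induced within minutes by touch, cold or wounding were described as a group because STZ, AT5G51190 and AT4G29780 were among the largest falls. Of 16 tested genes of this kind, 5 fell and 1 rose (6 and 2 adjusted over the list alone; camera adjusted p = 0.099, so the list was not called; adjusted p = 0.21 with an estimated correlation). ERF5 fell from 7.70 ± 0.75 to 3.78 ± 0.29 CPM (SD, n = 3; log2 fold change -1.03, SE 0.17), SZF1, a zinc finger gene, from 28.6 ± 1.38 to 17.0 ± 0.98 CPM (-0.75, SE 0.08), CAF1a, a deadenylase gene, from 18.7 ± 1.67 to 11 ± 1.22 CPM (-0.76, SE 0.11) and DIC2 from 9.79 ± 0.61 to 5.22 ± 0.75 CPM (-0.90, SE 0.15), while CML12, a calmodulin-like touch gene, rose by 0.33.

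Some floral organ genes were detectable in the aerial parts of both genotypes at day 9, and most of those tested were at a higher level in cpl2-2. Of 10 such genes, 4 had enough counts for the test and 3 rose (4 adjusted over the list alone): SEP3 from 2.32 ± 0.69 to 9.68 ± 1.14 CPM (2.06, SE 0.19, adjusted p = 1.2e-12), SEP1 from 1.40 ± 0.27 to 4.27 ± 0.48 CPM (1.6, SE 0.25) and SEP4 from 14 ± 0.59 to 20.2 ± 0.72 CPM (0.53, SE 0.10). PI was at 0.604 ± 0.198 and 1.14 ± 0.227 CPM (adjusted p = 0.11). CAL had 3 counts over the wild-type and 16 over the cpl2-2 libraries (ratio 5.41, 95% counting interval 1.55 to 28.95) and AP3 had 1 and 14 (14.2, interval 2.16 to 600).

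The genotype split of the 6 libraries called 5277 genes, and the highest count of any other split into 3 and 3 was 0 with edgeR (310 to 407 genes at an unadjusted p under 0.05); that is 1 split of 10, and 10 splits are too few for a share under 0.05.

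Rises of 2-fold or more outnumbered falls by 592 to 98. Among the 99 genes changed 2-fold or more with a mean of at least 10 CPM over both genotypes, 90.9% rose (exact 95% interval 83.4 to 95.8). The excess was thus not confined to genes with few counts in both genotypes. That cut keeps genes near the floor in the wild type that rose, such as AT1G18830 (0.163 to 90.1 CPM). Such genes can rise but not fall. Of the 592 rises, 320 had a mean under 1 CPM in the wild type. The remaining rises, at 1 CPM or more there, still outnumbered all 98 falls. Genes under 1 CPM in the wild type thus did not make up the whole excess. Library totals gave 672 rises and 83 falls, which bears on scaling and not on low counts. Chromosome stretches carried over from another accession would crowd the genes changed 2-fold or more. These genes fill 209 windows of 500 kb, or 102.5% of the median of random draws (range 191 to 214 windows), so most of them do not lie in a few stretches. With so many genes and windows, a few stretches holding a part of the genes would barely change that count. Such stretches were therefore not excluded. Reads running on from an expressed upstream neighbour on the same strand would place the genes that rose behind such neighbours. The odds ratio of lying within 1 kb downstream of such a neighbour was 0.81 within abundance classes (95% interval 0.66 to 0.998). As a set, the genes that rose therefore did not lie behind such neighbours more often. The rises were pooled, so reads running on into a part of them, or from further away, were not excluded. Reads from neighbours on the opposite strand, which could be counted too as the strand setting is not given, were not tested. The cause of the excess stays open, and a second mutation in the line was not tested.

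FLC and MAF5 were lower while FT, HSP70 and PR1 were higher, a combination known, as background, from plants that lack the SWR1 complex, which places the histone variant H2A.Z. Loss of a SWR1 or H2A.Z transcript was tested as its source. The rule, written after the values were seen, asked for 1 of the 14 genes at a log2 fold change under -1. All 14 were tested, and the lowest was HTA11, an H2A.Z gene, at a log2 fold change of -0.39 (79.9 ± 4.42 to 61.1 ± 2.58 CPM), with -0.65 as the lowest value less 2 SE for any of the 14. No transcript of the 14 thus fell 2-fold. CPL2, which the labels call knocked out, was itself at -0.82 in these whole-gene counts. A knocked-out gene need not fall under -1, so the test cannot decide whether any of the 14 was lost. HTA11 and ARP6 fell and YAF9B rose (5 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.099, adjusted p = 0.28 with an estimated correlation). The activity of the complex and the placing of H2A.Z were not measured and stay open.

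In the clock list 11 of 21 tested genes were lower and 3 higher, and of these GI, PRR5, PRR7, LNK1 and FKF1, picked after their values were seen, peak in the afternoon. A later phase of the day in cpl2-2 was tested on 4 other afternoon genes, and 3 of the 4 were called lower: PIF4 (-0.63, SE 0.15), COR27 (-0.22, SE 0.06) and COR28 (-0.30, SE 0.10), but not PIF5 (-0.26, SE 0.14, adjusted p = 0.18). An earlier phase would lower afternoon genes as well, and the evening genes were divided, with ELF4 (0.46) and BOA (0.33) higher and LUX (-0.38) and TOC1 (-0.26) lower. A later phase, an earlier phase and a change without a shift in phase therefore cannot be told apart, as the time of harvest is not given.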
